A study of Mus musculus with 16 samples.

How the data were processed

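The series measured RNA of mouse retina on 16 Affymetrix 3' expression arrays, with 1 array for each of 16 samples. Per the labels, BALB/c mice that were wild type or lacked Nxnl1, aged 11-16 weeks and of both sexes, were kept in darkness for 16 h, exposed to white fluorescent light of 50, 2500 or 5000 lux for 1 h, and left in the dark for 24 h. The neural retina was then separated from the retinal pigment epithelium (RPE), and RNA was purified on a cesium chloride gradient. The values are intensity values deposited by the authors, 1 per probe set and array, on a linear scale. The submitters' processing notes name GCRMA, a method of background correction, normalization and summarisation; its version and settings are not given in the sources used here. A single common lowest value of 4.62 filled between 30.9% and 31.5% of each array, and 9439 of the 45037 probe sets lay at that value on every array. Median intensity per array ran from 14.4 to 15.8. It lay between 14.4 and 15.1 on the 50 lux arrays and between 15.3 and 15.8 on all others. Each light response was therefore taken across this small shift. The number of arrays, not a counting depth, limits the precision.

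Log2 was taken of every value. Probe sets above log2 4 (an intensity of 16) on at least 2 arrays were tested, which kept 23320. In the probe set annotation used here 34945 probe sets had 1 gene symbol, 932 had several and 9160 had none. Of those tested, 19669 had 1 symbol and covered 10916 genes. The brightest probe set with 1 symbol, by its mean over all 16 arrays, stood for each gene.

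A linear model with a mean for each of the 6 groups was fitted to all 16 arrays in limma 3.58.1 under R 4.3.3, with empirical Bayes moderation and no intensity trend (10 residual degrees of freedom, 3.18 prior degrees of freedom). Each comparison was 1 contrast of that fit. Adjusted p is the Benjamini-Hochberg value over all probe sets tested in that contrast, and 0.05 was the threshold. The 12 contrasts were the light response at 2500 and at 5000 lux against 50 lux in each genotype, the step from 2500 to 5000 lux in each genotype, the genotype difference at each dose and averaged over the 3 doses, and the interaction of genotype with each light response. The p-values treat the labelled biological replicates as independent. The labels do not state whether an array held RNA of 1 animal or of a pool. On 10 arrays Y-linked genes and Xist both gave signal, as RNA of both sexes together would, which speaks for more than 1 animal there. The arrays were treated as unpaired. Log2 changes are given with the standard error (SE) of the fit, group levels with the standard deviation (SD).

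Gene lists were fixed before the data were examined, as were the tests, the rule for named genes and most of the other settings tried. The lists covered retinal cell types (rods, cones, genes shared by photoreceptors, Müller glia, bipolar, amacrine, ganglion and horizontal cells, endothelial cells and pericytes, microglia and macrophages), responses to injury (glial reactivity and injury cytokines, interferon response, complement and antigen presentation, chemokines and cytokines, immediate early and AP-1 genes), cell stress and metabolism (oxidative stress defence, the thioredoxin family, apoptosis and p53 targets, unfolded protein response, heat shock, cholesterol synthesis, glycolysis, circadian genes), crystallins, and markers of carry-over or sample makeup (RPE, lens fibre, blood, sex-linked). Lists were tested with camera in limma with a preset correlation of 0.01, on 1 probe set per gene, with Benjamini-Hochberg adjustment over the 26 lists tested in each contrast; each test was repeated with the estimated correlation. The lens fibre and blood lists had 1 measured member each and were not tested as lists. List medians and SDs are taken across the measured members.

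In each comparison the named genes were Nxnl1 and Nxnl2, up to 15 genes with the largest rise and up to 15 with the largest fall among those past the threshold whose groups did not overlap (past the threshold alone for interactions and for the mean over doses), and the 4 members of each list with the smallest p. Where under 5 genes passed, the 5 with the smallest p were eligible as not passing. Probe sets without a symbol are counted and not named. Where every array of 1 group of a comparison lay at or below log2 4, its values were raised to that level and the fold is given as a lower bound, in the words "at least". Where both group means were below log2 4, no fold is given.

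The fit was tested on simulated data with the group sizes of the series, 200 changed probe sets and 10 draws. The changed probe sets were drawn from those with a mean above log2 6, and the noise was independent between probe sets and between arrays. The shares recovered therefore do not cover dimmer probe sets, and no share below covers variation that many probe sets have in common. In the genotype comparison at 50 lux it recovered 75.3% of 2-fold and 98.8% of 4-fold changes, and in the genotype comparison at 2500 lux 83.3% and 99.4%. In the wild-type light response at 2500 lux it recovered 72.3% and 98.1%, and in the knockout light response at 5000 lux 74.6% and 97.9%. Unchanged probe sets made up 5.64%, 5.43%, 5.07% and 5.06% of the calls in these 4 comparisons.

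Other settings, fixed in advance, were a fit on the arrays of the contrast's groups alone, no filter, a filter at log2 6, an intensity trend with robust estimation, quantile normalization applied again, array weights, the labels' replicate number as a block, a sex covariate from Y-linked genes and Xist, log2 of the value plus 16, the mean of a gene's probe sets for the lists, an adjusted p threshold of 0.01 for the overlap of both genotypes, the other probe sets of each named gene, and leaving out each array in turn. Added after seeing the data were a crystallin covariate, an RPE covariate, and the removal of 2 arrays in doubt (wild-type 5000 lux replicate 2, which had the highest crystallin levels, and knockout 50 lux replicate 1, which lay farthest from its group on the second principal component). Python and matplotlib drew the figures.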

Results

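The 16 arrays fell into 6 groups by genotype and light dose. Wild-type retinas had 2 arrays at 50 lux, 3 at 2500 lux and 3 at 5000 lux, and retinas of mice without Nxnl1 (knockout) had 3, 3 and 2. The series text speaks of triplicates and of 2 light doses, and why 2 groups had 2 arrays is not given in the sources used here. Nxnl1 encodes the rod-derived cone viability factor, a thioredoxin-like protein made by rods that helps cones survive. The dose of 50 lux was the light in which the animals were raised, so the groups at 50 lux served as the reference for each light response. The first principal component held 41.1% of the variance and separated all 5 arrays at 50 lux from the 11 arrays at the higher doses; its group means were -48.3 and -52.1 at 50 lux and ran from 17.0 to 30.8 at the higher doses.

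The targeted gene was measured first. The brighter Nxnl1 probe set had a log2 level of 7.57 ± 0.06 (SD, n = 2) in wild-type retinas at 50 lux, 6.44 ± 0.53 (n = 3) at 2500 lux and 6.06 ± 0.39 (n = 3) at 5000 lux. In knockout retinas it lay at 2.24 on all 3 arrays at 50 lux, at 2.45 ± 0.36 (n = 3) at 2500 lux and at 2.57 ± 0.50 (n = 2) at 5000 lux. The highest knockout array was at 2.92 and the lowest wild-type array at 5.64. Nxnl1 was at least 11.9-fold lower in knockout retinas at 50 lux, at least 5.43-fold lower at 2500 lux and at least 4.17-fold lower at 5000 lux, with adjusted p of 4.4e-06, 4.1e-05 and 0.00082. A second Nxnl1 probe set did not exceed log2 3.34 on any array and was not tested. The part of Nxnl1 removed in the knockout, and whether these probes lie in it, is not given in the sources used here.

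**Figure D1:**
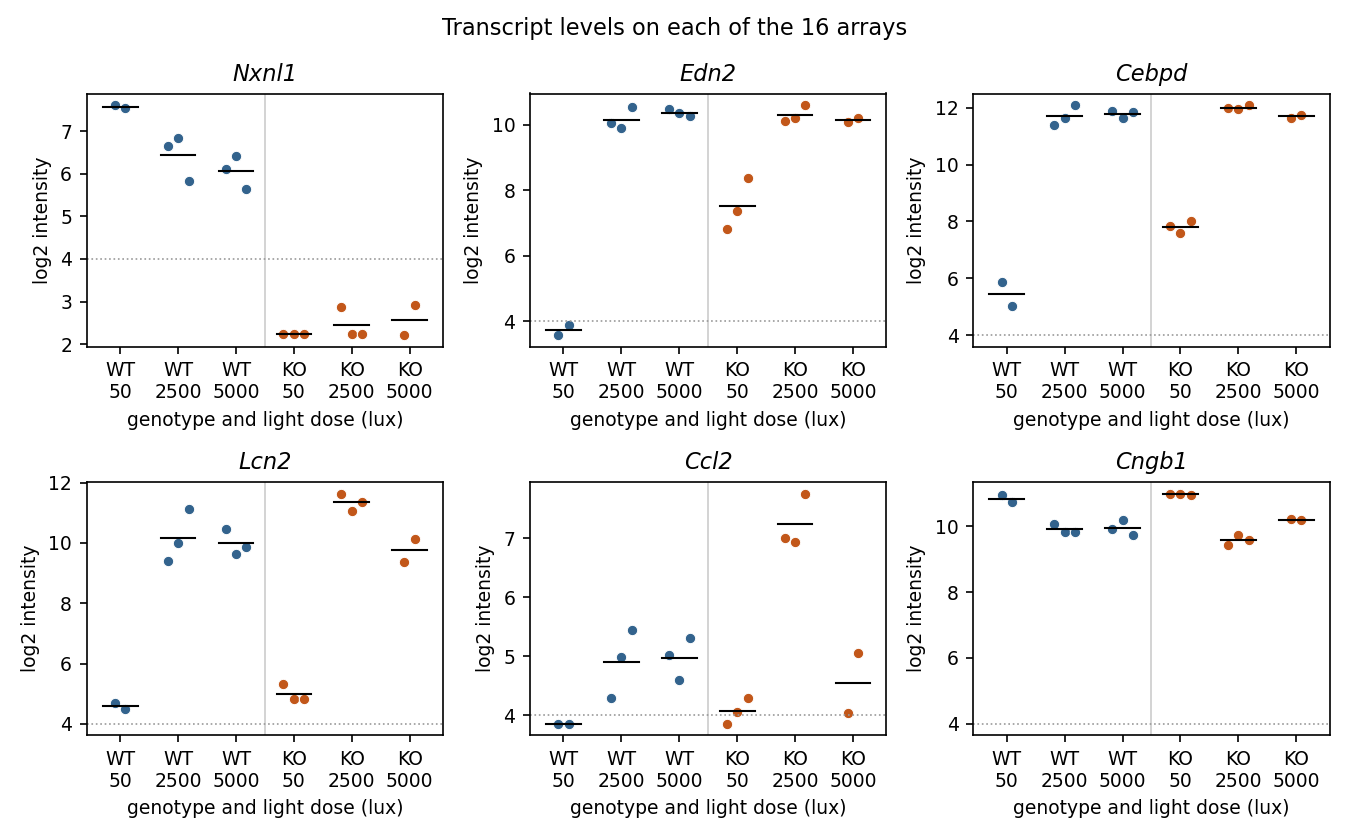
Log2 intensity of 6 transcripts on each array (points) with group means (bars), for wild-type (WT, blue) and knockout (KO, orange) retinas at 50, 2500 and 5000 lux; the dotted line marks log2 4. Nxnl1 was at most 2.92 on the knockout arrays, and Edn2 had a mean of 3.73 in wild-type and 7.52 in knockout retinas at 50 lux and means of 10.1 to 10.4 in the groups at the higher doses.

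The comparison of 2500 with 50 lux in wild-type retinas (n = 3 against 2) asked what bright light did to the retina 24 h later. Edn2, which encodes an endothelin released by stressed photoreceptors, rose at least 71.2-fold (adjusted p = 1.3e-07). The transcription factor Cebpd rose 75.8-fold (log2 change 6.24, SE 0.23, adjusted p = 8.6e-09), and Socs3, a brake on cytokine signalling, rose 49.2-fold (log2 5.62, SE 0.35, adjusted p = 3.6e-07). The acute-phase genes Lcn2 (log2 5.58, SE 0.40) and Serpina3n (at least 24.8-fold) rose as well, with adjusted p of 1.7e-06 and 2.8e-07.

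All 20 measured genes of glial reactivity and injury cytokines rose in wild-type retinas at 2500 lux (20 adjusted over the list alone), with a median log2 change of 3.07 (SD 1.69), as did all 14 interferon response genes (14 adjusted over the list alone), with a median of 2.74 (SD 0.82). Bst2, an antiviral membrane protein, rose at least 6.01-fold, and the guanylate-binding protein gene Gbp2 rose 13.0-fold (log2 3.70, SE 0.35, adjusted p = 1.4e-05; 1 of 2 arrays at 50 lux was above log2 4). Of 11 complement and antigen presentation genes 9 rose (10 adjusted over the list alone); Serping1, which encodes the C1 inhibitor, rose at least 17.9-fold and B2m, the light chain of class I molecules, rose 7.13-fold. Of 10 chemokine and cytokine genes 7 rose (8 adjusted over the list alone), among them Ccl12, at least 3.40-fold, and Vcam1, 4.31-fold. Of 16 immediate early and AP-1 genes 6 rose (10 adjusted over the list alone), led by Junb (log2 3.36, SE 0.32) and Atf3 (log2 3.33, SE 0.29). These 5 lists were called by camera (adjusted p = 4.2e-29, 3.7e-18, 5.4e-10, 8.2e-07 and 2.0e-05) and stayed called with an estimated correlation. Of 12 microglia and macrophage genes 5 rose (6 adjusted over the list alone), including Lgals3 (log2 4.75, SE 0.37) and Cd68, at least 2.31-fold; camera gave adjusted p = 7.6e-05, and 0.14 with an estimated correlation.

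Photoreceptor genes fell by smaller amounts in the same wild-type comparison. Of 13 rod phototransduction genes 8 fell (13 adjusted over the list alone), with a median log2 change of -0.54 (SD 0.24). The cyclic GMP-gated channel subunit Cngb1 fell 1.90-fold (log2 -0.93, SE 0.14, adjusted p = 0.00088) and the phosphodiesterase subunit Pde6b fell 1.45-fold (log2 -0.54, SE 0.10, adjusted p = 0.0037). Of 25 genes shared by photoreceptors 15 fell and 1 rose (16 and 1 adjusted over the list alone), with Gucy2e, a retinal guanylate cyclase, at least 1.99-fold lower. Of 13 cone genes 4 fell and 1 rose (5 and 1 adjusted over the list alone): the cone arrestin Arr3 fell by 1.49 on the log2 scale (SE 0.29, adjusted p = 0.0044), while Gnb3, the cone transducin beta subunit, rose by 1.13 (SE 0.14, adjusted p = 0.00013). The rod and shared lists were called (adjusted p = 1.4e-09 and 3.1e-09) and stayed called with an estimated correlation (adjusted p = 0.049 for each); the cone list had adjusted p = 0.017, and 0.42 with an estimated correlation. Nxnl1 itself fell 2.19-fold (adjusted p = 0.030) and its relative Nxnl2 fell 1.67-fold (adjusted p = 0.0010). Of 13 RPE markers, which measure tissue left on the retina, 3 fell (3 fell and 1 rose adjusted over the list alone), with Rpe65 lower by a log2 change of -1.82 (SE 0.51, adjusted p = 0.036).

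Of 21 oxidative stress defence genes in wild-type retinas at 2500 lux 5 rose and 1 fell (6 and 1 adjusted over the list alone), led by the metallothionein Mt2 (log2 2.16, SE 0.29) and Hmox1, at least 2.20-fold; camera gave adjusted p = 0.027, and 0.52 with an estimated correlation. Of 15 Müller glia genes 3 rose and 6 fell (the same counts adjusted over the list alone), with Vim, an intermediate filament of reactive glia, up by 1.97 (SE 0.12) and Rlbp1, a retinoid carrier, down at -1.37 (SE 0.12). Glycolysis genes fell in 3 of 17 (4 adjusted over the list alone; adjusted p = 0.0054 for the list, and 0.47 with an estimated correlation), and 1 of 10 endothelial and pericyte genes, Kdr, rose (1 adjusted over the list alone; adjusted p = 0.043 for the list, and 0.51 with an estimated correlation). Lists without a call had 4 of 13 apoptosis and p53 targets up (5 up and 2 down adjusted over the list alone), among them Gadd45b (log2 3.63, SE 0.30), and 2 of 18 thioredoxin family genes up and 1 down. Heat shock had 2 of 12 up, the unfolded protein response 2 of 14 up, cholesterol synthesis 1 of 14 up, circadian genes 1 of 15 up and 1 down, and ganglion cell genes 1 of 11 up. Adjusted over the list alone these last 6 counts were the same, except for 3 circadian genes up and 3 down. None of 12 bipolar, 10 amacrine, 4 horizontal cell, 4 sex-linked and 11 crystallin genes passed in limma at this dose, over all genes or adjusted over the list alone. The blood list's measured member, the globin Hba-a2, passed as higher (adjusted p = 0.0086) with both group means below log2 4, and the lens fibre member Grifin had a log2 change of -0.03 (SE 1.25, adjusted p = 0.996).

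In limma 1568 probe sets rose and 1176 fell among 23320 in wild-type retinas at 2500 lux, covering 975 and 560 genes. The reference group had 2 arrays. Without wild-type 50 lux replicate 1 the calls numbered 1127, and without replicate 2 they numbered 1297; of 90 named genes past the threshold 60 stayed past it whichever array was left out, and of those cited above Nxnl1, Arr3, Rpe65 and Hba-a2 did not (adjusted p = 0.17, 0.050, 0.25 and 0.11 without wild-type 50 lux replicate 1). With only these 5 arrays in the fit 1275 probe sets were called.

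At 5000 lux wild-type retinas (n = 3 against 2) had a response of similar make. Edn2 was at least 82.7-fold higher (adjusted p = 7.4e-08), Cebpd 80.8-fold (log2 6.34, SE 0.23) and S100a6, a calcium-binding protein, 75.8-fold (log2 6.24, SE 0.31). The largest falls included Glb1l3 (log2 -3.37, SE 0.40, with 1 of 3 arrays above log2 4 at 5000 lux) and the basement membrane collagen Col4a3 (log2 -2.67, SE 0.32). All 20 glial reactivity genes and all 14 interferon genes rose (20 and 14 adjusted over the list alone), with medians of 3.21 (SD 1.71) and 2.74 (SD 0.85). Complement genes rose in 8 of 11 (10 adjusted over the list alone), chemokines in 7 of 10 (8), AP-1 genes in 7 of 16 (11) and microglial genes in 5 of 12 (5). Of these 6 lists, glial reactivity, interferon, complement and AP-1 genes stayed called with an estimated correlation (adjusted p = 0.029 for each); chemokines had adjusted p = 0.055 and microglia 0.23 with an estimated correlation.

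Photoreceptor and RPE transcripts fell in the same wild-type arrays at 5000 lux. Of 13 rod genes 10 fell (12 adjusted over the list alone; median log2 -0.55, SD 0.33), with Pde6a, a catalytic subunit of the rod phosphodiesterase, at -1.43 (SE 0.20, adjusted p = 0.00039). Genes shared by photoreceptors fell in 13 of 25 (16 fell and 1 rose adjusted over the list alone), and cone genes fell in 4 of 13 with Gnb3 again higher (5 and 1 adjusted over the list alone). Camera called the rod, shared and cone lists (adjusted p = 2.8e-09, 3.0e-07 and 0.020), which with an estimated correlation had adjusted p = 0.055, 0.060 and 0.45. Nxnl1 fell 2.85-fold (log2 -1.51, SE 0.31, adjusted p = 0.0062, and 0.066 without wild-type 50 lux replicate 1) and Nxnl2 1.66-fold (log2 -0.73, SE 0.12, adjusted p = 0.0011). RPE markers fell in 8 of 13 (8 fell and 1 rose adjusted over the list alone; median log2 -1.38, SD 0.93; adjusted p = 0.00032 for the list, and 0.35 with an estimated correlation). Rpe65, the RPE isomerase of the visual cycle, fell 7.04-fold (log2 -2.82, SE 0.51, adjusted p = 0.0031). Oxidative stress defence genes rose in 5 of 21 (6 up and 1 down adjusted over the list alone; adjusted p = 0.0099, and 0.48 with an estimated correlation), and the glycolysis list was called lower with 0 of 17 members past the threshold in limma (adjusted p = 0.028, and 0.59 with an estimated correlation). Cryab, a small heat shock protein of the crystallin list, rose 5.99-fold (adjusted p = 0.041, and 0.18 without wild-type 50 lux replicate 1). No other of the 11 crystallins passed, and the list, with a median log2 change of 3.01 (SD 0.35), was not called (adjusted p = 0.061). Its mean level without Cryab was 12.7 in wild-type 5000 lux replicate 2, against 2.57 and 3.49 in the other 2 replicates. At 50 lux it was 2.73 and 3.78.

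In limma 1393 probe sets rose and 1054 fell in wild-type retinas at 5000 lux, covering 825 and 575 genes. Calls numbered 1025 without wild-type 50 lux replicate 1, 1284 without replicate 2, 1569 without wild-type 5000 lux replicate 3 and 5512 with array weights. Of 87 named genes past the threshold 59 stayed past it whichever array was left out; Rpe65 had adjusted p = 0.054 without wild-type 50 lux replicate 1.

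The same question was asked in knockout retinas at 2500 lux (n = 3 against 3). Lcn2 rose 82.1-fold (log2 6.36, SE 0.36, adjusted p = 2.3e-07) and Prss56, a serine protease of Müller glia, rose 79.4-fold (log2 6.31, SE 0.69, adjusted p = 3.1e-05). Socs3 rose 50.8-fold (log2 5.67, SE 0.31) and Cebpd 18.3-fold (log2 4.19, SE 0.21). The chemokine Ccl2, which draws monocytes, rose 8.97-fold (log2 3.17, SE 0.32, adjusted p = 1.8e-05), and Hmox1, which degrades heme, at least 5.02-fold. Among the largest falls were Glb1l3, at least 11.2-fold lower, Col4a3 (log2 -3.55, SE 0.29), the pigment cell receptor Mc1r (log2 -2.89, SE 0.21, with 1 of 3 arrays above log2 4 at 2500 lux) and the short-wavelength cone opsin Opn1sw (log2 -2.30, SE 0.35, adjusted p = 0.00050).

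Every measured glial reactivity gene (20 of 20, and 20 adjusted over the list alone) and interferon gene (14 of 14, and 14) rose in knockout retinas at 2500 lux, with medians of 3.11 (SD 1.52) and 2.66 (SD 0.72). Chemokines rose in 8 of 10 (8 up and 1 down adjusted over the list alone), complement genes in 8 of 11 (8) and AP-1 genes in 10 of 16 (11). These 5 lists stayed called with an estimated correlation (adjusted p = 0.028, 0.028, 0.046, 0.049 and 0.038). Oxidative stress defence genes rose in 9 of 21 (10 up and 3 down adjusted over the list alone), microglial genes in 4 of 12 with 1 down (4 and 2), and apoptosis genes in 6 of 13 with 1 down (6 and 1). Those 3 lists had adjusted p = 0.00024, 0.0014 and 0.0045, and 0.27, 0.25 and 0.12 with an estimated correlation. Rod genes fell in 13 of 13 (13 adjusted over the list alone; median log2 -0.83, SD 0.30), shared photoreceptor genes in 15 of 25 (15) and cone genes in 8 of 13 with Gnb3 higher (8 down and 2 up adjusted over the list alone). Cngb1 fell 2.61-fold (log2 -1.38, SE 0.13) and Arr3 4.30-fold (log2 -2.10, SE 0.26, adjusted p = 8.1e-05). The rod, shared and cone lists had adjusted p = 8.9e-09, 7.6e-06 and 0.0049, and 0.061, 0.11 and 0.31 with an estimated correlation. RPE markers fell in 2 of 13, with 1 up, and were not called as a list (adjusted p = 0.45).

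In limma 2005 probe sets rose and 2496 fell in knockout retinas at 2500 lux, covering 968 and 1477 genes. Calls numbered 2918 without knockout 2500 lux replicate 3 and 6791 with array weights; of 96 named genes past the threshold 87 stayed past it whichever array was left out.

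In knockout retinas at 5000 lux (n = 2 against 3) Lcn2 rose 26.9-fold (log2 4.75, SE 0.40, adjusted p = 1.7e-05), Socs3 23.4-fold (log2 4.55, SE 0.35) and Cebpd 14.7-fold (log2 3.88, SE 0.23). Glial reactivity genes rose in 19 of 20 (20 adjusted over the list alone; median log2 2.56, SD 1.27) and interferon genes in 14 of 14 (14; median 1.68, SD 0.66). Complement genes rose in 6 of 11 (8), chemokines in 6 of 10 (7 up and 1 down adjusted over the list alone), AP-1 genes in 6 of 16 (8) and microglial genes in 4 of 12 with 1 down (4 and 2). The glial, interferon and AP-1 lists stayed called with an estimated correlation (adjusted p = 0.028, 0.036 and 0.040), and complement, chemokines and microglia had adjusted p = 0.083, 0.11 and 0.48 with an estimated correlation. Rod genes fell in 7 of 13 (9 adjusted over the list alone; adjusted p = 0.00039, and 0.39 with an estimated correlation), with Cngb1 1.71-fold lower (log2 -0.77, SE 0.14, adjusted p = 0.0053). Ganglion cell genes fell in 4 of 11 (10 adjusted over the list alone), among them Thy1 (log2 -1.60, SE 0.36, adjusted p = 0.014), and amacrine genes in 5 of 10 (7), among them the GABA transporter of synaptic vesicles Slc32a1 (log2 -0.99, SE 0.27, adjusted p = 0.031). Those 2 lists had adjusted p = 0.00037 and 0.0062, and 0.48 and 0.60 with an estimated correlation. Bipolar cell genes had 1 of 12 and horizontal cell genes 1 of 4 down (1 down, and 2 down and 1 up, adjusted over the list alone), and neither list was called (adjusted p = 0.94 for each, and 0.97 with an estimated correlation). Cone genes fell in 4 of 13 with 1 up (6 and 1 adjusted over the list alone), shared photoreceptor genes in 4 of 25 with 1 up (8 and 1) and no RPE marker passed in limma; these lists were not called (adjusted p = 0.19, 0.28 and 0.33).

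In limma 1291 probe sets rose and 1372 fell in knockout retinas at 5000 lux. This count rested on the 2 arrays of the dose: it was 4411 without knockout 5000 lux replicate 1, 575 without replicate 2, 1470 without knockout 50 lux replicate 1 and 182 with only these 5 arrays in the fit. Of 87 named genes past the threshold 45 stayed past it whichever array was left out, and without knockout 5000 lux replicate 2 Thy1 had adjusted p = 0.19 (log2 -1.09), Slc32a1 0.31 (log2 -0.65) and Cngb1 0.058.

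Both genotypes responded alike in direction. Across probe sets, which are not independent replicates, the log2 changes at 2500 lux of the 2 genotypes had r = 0.745, and at 5000 lux r = 0.682; the 2 responses used separate arrays. At 2500 lux 1073 probe sets rose in both genotypes, against 134.8 if the calls were independent, 785 fell in both, against 125.9, and 1 moved in opposite directions. At 5000 lux 691 rose in both, against 77.1, 444 fell in both, against 62.0, and 2 moved in opposite directions. At an adjusted p of 0.01 the counts up in both were 646 at 2500 lux and 382 at 5000 lux, against 42.1 and 16.0. Socs3, Lcn2, Serpina3n, Bcl3, S100a6, Lad1 and Lgals3 were among the largest rises in all 4 light comparisons, and Glb1l3, Col4a3, Hcls1 and Mir670hg among the largest falls in all 4.

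**Figure D2:**
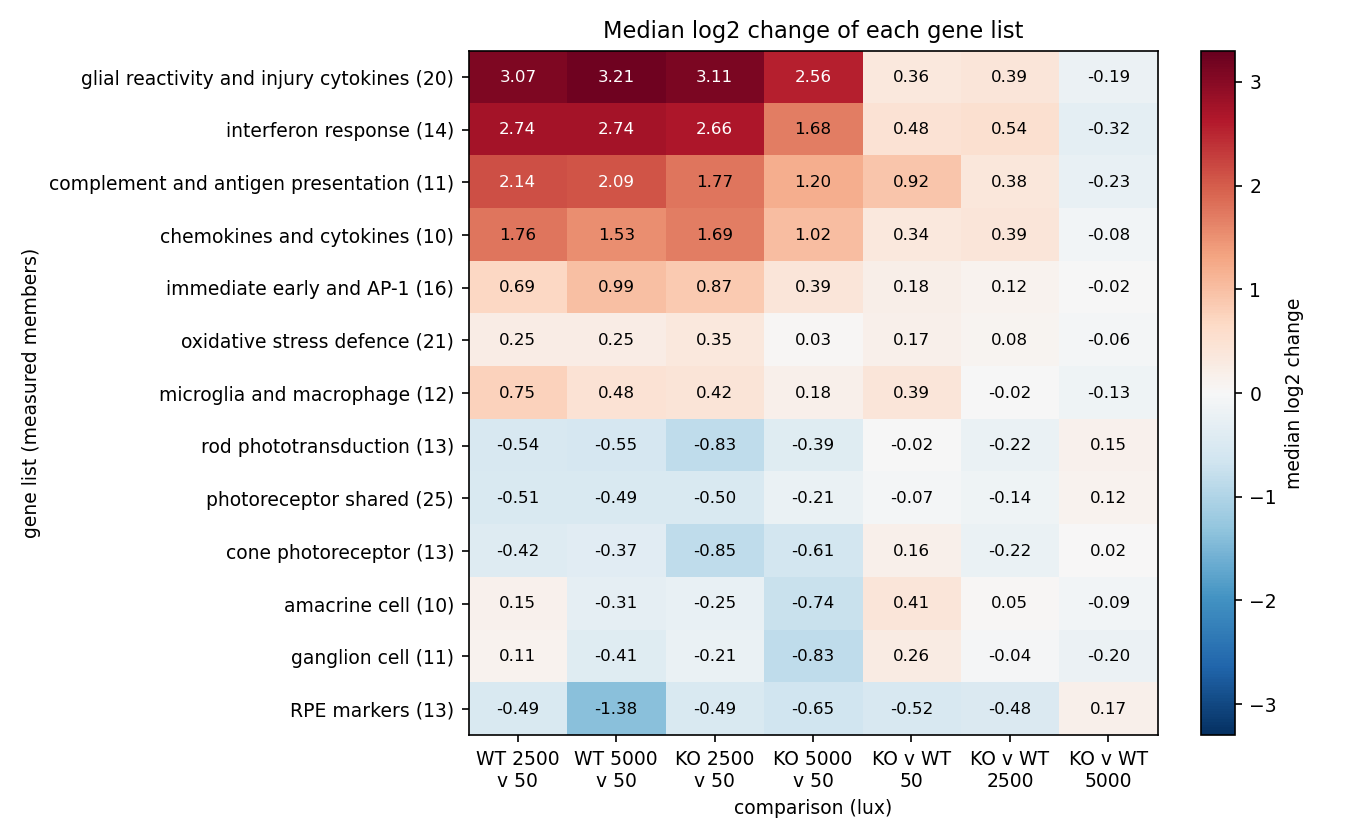
Median log2 change of 13 gene lists (number of measured genes in brackets) in the 4 light comparisons and the 3 genotype comparisons; red marks higher and blue lower medians. Glial reactivity genes had medians from 2.56 to 3.21 in the 4 light comparisons and rod genes from -0.83 to -0.39.

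The step from 2500 to 5000 lux asked whether more light changed the response further. In wild-type retinas (n = 3 against 3) limma called 0 probe sets, with a smallest adjusted p of 0.38. At an unadjusted p under 0.05 there were 1917 of 23320, a share above 0.05, so the lack of calls does not show that the doses were alike. Edn2 differed between these doses by 0.22 on the log2 scale (SE 0.30) and Cebpd by 0.09 (SE 0.21), neither past the threshold. Without wild-type 5000 lux replicate 1 the count was 30, and without wild-type 2500 lux replicate 3 it was 1. Camera called 4 lists: crystallins higher (median log2 3.34, SD 1.04, adjusted p = 2.1e-05), and RPE markers (median -0.78, SD 0.43, adjusted p = 0.00021), ganglion cell genes (median -0.43, SD 0.26, adjusted p = 0.0017) and amacrine genes (median -0.37, SD 0.27, adjusted p = 0.0048) lower. With an estimated correlation these had adjusted p = 0.70, 0.70, 0.70 and 0.71, and no member of the 4 lists passed in limma; adjusted over the list alone 3 RPE markers and 1 ganglion cell gene fell. The crystallin call was lost without wild-type 5000 lux replicate 2.

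In knockout retinas (n = 2 against 3) the same step was tested. Ccl2 fell 6.44-fold (log2 -2.69, SE 0.36, adjusted p = 0.016), the retinaldehyde dehydrogenase Aldh1a3 at least 2.11-fold, Hmox1 4.19-fold (log2 -2.07, SE 0.29), the opioid precursor Penk 3.84-fold (log2 -1.94, SE 0.22, adjusted p = 0.013) and the interferon gene Ifit2 2.34-fold (log2 -1.23, SE 0.20, adjusted p = 0.036). In limma 17 probe sets fell and 1 rose. Glial reactivity genes had a median of -0.68 (SD 0.50; 0 of 20 past the threshold in limma, 11 down adjusted over the list alone) and interferon genes a median of -0.79 (SD 0.33; 1 of 14 down, 12 adjusted over the list alone). Rod genes (median 0.38, SD 0.14; none past, 8 up adjusted over the list alone) and shared photoreceptor genes (median 0.33, SD 0.20; none past, 9 up adjusted over the list alone) lay higher. Camera called 12 lists, with adjusted p = 8.2e-10, 1.2e-09, 8.2e-10 and 2.1e-10 for these 4; with an estimated correlation no list was called, and these 4 had adjusted p = 0.20, 0.14, 0.13 and 0.11. Ganglion cell genes (median -0.61, SD 0.27) and amacrine genes (median -0.54, SD 0.18) were called lower as well, with no member past over all genes or adjusted over the list alone (adjusted p = 0.00036 and 0.00027, and 0.35 and 0.33 with an estimated correlation). The other 6 called lists were cone genes, higher, and complement, microglial, chemokine, oxidative stress and apoptosis genes, lower. All 13 named genes lost their call without knockout 5000 lux replicate 2, where limma called 0 probe sets (Ccl2 had adjusted p = 0.092), and without replicate 1 it called 103.

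The genotype comparison at 50 lux (n = 3 knockout against 2 wild type) asked whether loss of Nxnl1 altered the retina before bright light. Edn2 was at least 11.4-fold higher in knockout retinas (adjusted p = 0.00020), with levels of 7.52 ± 0.78 (SD, n = 3) against 3.73 ± 0.22 (SD, n = 2). Cebpd was 5.12-fold higher (log2 2.36, SE 0.23, adjusted p = 0.00058), Nudt6 4.93-fold (log2 2.30, SE 0.14, adjusted p = 6.4e-06) and Sox30 2.72-fold (log2 1.44, SE 0.14, adjusted p = 0.00040). Nudt6 overlaps Fgf2, a photoreceptor survival factor, on the genome, and it is uncertain which transcript its probe set read; a second Nudt6 probe set had a log2 change of 0.37 (adjusted p = 0.54). Further rises were S100a6 (log2 1.88, SE 0.31), Rnase4 (log2 1.55, SE 0.23) and Antxr2 (log2 1.42, SE 0.17). Bst2, which lies on the chromosome of Nxnl1, passed as higher (adjusted p = 0.047) with both group means below log2 4, so no size is given. Besides Nxnl1, the largest falls were Fabp4 (log2 -1.70, SE 0.26), Gucy2e, at least 1.99-fold lower, and BE949265, at least 1.28-fold lower, and Nxnl2 fell by 0.62 on the log2 scale (SE 0.12, adjusted p = 0.044).

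By lists at 50 lux, glial reactivity genes had a median of 0.36 in knockout against wild-type retinas (SD 0.96; 2 of 20 up, 7 adjusted over the list alone), complement genes 0.92 (SD 0.39; none of 11 past, 6 up adjusted over the list alone) and interferon genes 0.48 (SD 0.48; 1 of 14 up, 5 adjusted over the list alone). Crystallins had a median of 3.18 (SD 1.45; none of 11 past in limma or adjusted over the list alone) and RPE markers -0.52 (SD 0.41; none of 13 past either way). Camera called these 5 lists (adjusted p = 0.0016, 0.00055, 0.019, 0.039 and 0.00015), and shared photoreceptor genes (median -0.07, 1 of 25 down, adjusted p = 0.00015) and glycolysis (median -0.02, adjusted p = 0.0082) as lower. With an estimated correlation none was called; adjusted p was 0.85, 0.50, 0.85, 0.85 and 0.56 for the first 5, and 0.48 and 0.85 for the others. In limma 48 probe sets were higher and 28 lower, covering 32 and 12 genes. None of the 48, Edn2, Cebpd, Nudt6 and Sox30 included, was called with only the 5 arrays of this comparison in the fit. The count was 9 without wild-type 50 lux replicate 2, 363 (134 higher and 229 lower) without knockout 50 lux replicate 2 and 1 with only these 5 arrays in the fit. Edn2, Cebpd, Nudt6, Sox30 and Nxnl1 stayed past the threshold whichever array was left out, and the other 22 of 27 named genes did not.

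At 2500 lux (n = 3 against 3) the question was how the genotypes differed after bright light. Ccl2 was 5.02-fold higher in knockout retinas (log2 2.33, SE 0.32, adjusted p = 0.018), Aldh1a3 at least 2.11-fold, the proto-oncogene Myc at least 2.07-fold, the secreted glutathione peroxidase Gpx3 at least 5.94-fold, Penk 2.95-fold (log2 1.56, SE 0.20, adjusted p = 0.013) and the endothelin receptor Ednrb 2.96-fold (log2 1.57, SE 0.26, adjusted p = 0.048). Besides Nxnl1, Dnaaf4 was lower (log2 -0.94, SE 0.13, adjusted p = 0.020). Glial reactivity genes had a median of 0.39 (SD 0.44; 1 of 20 up, 7 adjusted over the list alone), interferon genes 0.54 (SD 0.26; none of 14 past, 2 up adjusted over the list alone) and chemokines 0.39 (SD 0.71; 1 of 10 up, 3 adjusted over the list alone). Rod genes had a median of -0.22 (SD 0.11; none of 13 past, 3 down adjusted over the list alone) and cone genes -0.22 (SD 0.29; none of 13 past, 1 down adjusted over the list alone). On the same arrays RPE markers had a median of -0.48 (SD 0.36) and crystallins of 2.04 (SD 1.47), with no member past the threshold. These 7 lists were called by camera (adjusted p = 2.9e-12, 1.1e-09, 3.7e-05, 7.4e-07, 0.0012, 0.00081 and 0.0018) among 12; with an estimated correlation they had adjusted p = 0.17, 0.17, 0.17, 0.17, 0.24, 0.33 and 0.66. The other 5 were shared photoreceptor genes, lower, and complement, oxidative stress, AP-1 and apoptosis genes, higher. With an estimated correlation camera gave these 5 adjusted p = 0.18, 0.24, 0.24, 0.18 and 0.24.

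In limma 19 probe sets were higher and 3 lower in knockout retinas at 2500 lux. The count was 2 without wild-type 2500 lux replicate 1, 3 without replicate 2 and 86 without replicate 3; it was 5 and 6 without knockout 2500 lux replicates 2 and 3, and 4 with an RPE covariate. Nxnl1 stayed past the threshold whichever array was left out, and the other 14 named genes did not (Ccl2 had adjusted p = 0.13 without wild-type 2500 lux replicate 2).

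At 5000 lux (n = 2 against 3) Nxnl1 was the 1 probe set called between genotypes in limma. At an unadjusted p under 0.05 there were 540 of 23320, a share below 0.05, so they are no sign of further differences. The lack of calls does not show that the genotypes were alike. Calls numbered 2 without wild-type 5000 lux replicate 1 and 0 with only these 5 arrays in the fit. Rod genes had a median of 0.15 (SD 0.13) and shared photoreceptor genes 0.12 (SD 0.26) in knockout against wild type, and interferon genes -0.32 (SD 0.14) and glial reactivity genes -0.19 (SD 0.19), with no member past the threshold over all genes or adjusted over the list alone. Camera called these 4 lists (adjusted p = 3.5e-05, 0.00073, 0.00032 and 0.0054), and each had adjusted p = 0.75 with an estimated correlation.

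Averaged over the 3 doses, knockout retinas had less Nxnl1 (adjusted p = 4.2e-08) and BE949265 (adjusted p = 0.033) and more Nudt6 (log2 0.72, SE 0.08, adjusted p = 0.0074). By dose the Nudt6 difference was 2.30, 0.14 and -0.29 at 50, 2500 and 5000 lux. It passed the threshold at 50 lux only. Another probe set, without a symbol, was also higher. No size is given for Nxnl1, which was below log2 4 on all knockout arrays, or for BE949265, which was below it on all arrays but the 2 wild-type ones at 50 lux; BE949265 had adjusted p = 0.15 without wild-type 50 lux replicate 2. Glial reactivity genes had a median of 0.36 (SD 0.34; none of 20 past, 7 up adjusted over the list alone), complement genes 0.33 (SD 0.14; none of 11 past, 4 up adjusted over the list alone) and RPE markers -0.31 (SD 0.17; none of 13 past either way). Camera called these 3 (adjusted p = 1.0e-06, 0.00087 and 7.7e-05) among 8 lists, and each had adjusted p = 0.43 with an estimated correlation. Others of the 8 were interferon and chemokine genes, higher, and shared photoreceptor genes, lower. None of the 8 was called with an estimated correlation. The averages of the 3 lists given with medians held opposite signs by dose. At 50, 2500 and 5000 lux the medians were 0.36, 0.39 and -0.19 for glial reactivity, 0.92, 0.38 and -0.23 for complement and -0.52, -0.48 and 0.17 for RPE markers.

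The interaction tested whether the light response differed between genotypes. At 2500 lux the response in knockout retinas was lower than in wild type for Edn2 (interaction log2 -3.64, SE 0.45, adjusted p = 0.010), Rnase4 (log2 -2.66, SE 0.31, adjusted p = 0.0065), Nudt6 (log2 -2.16, SE 0.19, adjusted p = 0.0010), Cebpd (log2 -2.05, SE 0.31, adjusted p = 0.044) and Sox30 (log2 -1.39, SE 0.18, adjusted p = 0.018). At 5000 lux the same held for Edn2 (log2 -4.01, SE 0.47, adjusted p = 0.0060), Nudt6 (log2 -2.59, SE 0.20, adjusted p = 0.00022), Cebpd (log2 -2.46, SE 0.33, adjusted p = 0.022) and Sox30 (log2 -1.70, SE 0.19, adjusted p = 0.0057). Within knockout retinas Edn2, Nudt6, Cebpd and Sox30 rose at 2500 lux (log2 2.79, 2.28, 4.19 and 1.80) and at 5000 lux (log2 2.63, 2.10, 3.88 and 1.74). Rnase4 did not pass there at 2500 lux (log2 0.32, SE 0.20, adjusted p = 0.31). At 2500 lux Edn2 was at 10.15 ± 0.33 (SD, n = 3) in wild-type and 10.30 ± 0.26 (SD, n = 3) in knockout retinas, and Rnase4 at 7.45 ± 0.17 and 6.34 ± 0.18. Edn2 was below log2 4 in wild-type retinas at 50 lux, so the sizes of its interactions depend on the background level. The 50 lux arrays enter both the interactions and the genotype comparison at 50 lux, so these are not independent results.

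In limma the interaction held 3 probe sets up and 8 down at 2500 lux, and 6 down at 5000 lux. With no filter, which adds dim probe sets, the balance turned. There were then 37 up and 10 down at 2500 lux, and 31 up and 8 down at 5000 lux. At 2500 lux Nudt6 and Rnase4 kept their calls whichever array was left out. Edn2, Sox30 and Cebpd stayed past the threshold in 13, 12 and 3 of 16 removals. Without wild-type 50 lux replicate 1 the log2 changes of Edn2 and Sox30 were -3.48 and -1.19, and without replicate 2 that of Cebpd was -1.62. At 5000 lux Edn2, Nudt6 and Sox30 kept their calls in every removal. Cebpd stayed past the threshold in 7 of 16 removals, and its log2 change was -2.50 without knockout 5000 lux replicate 2. Camera called no list at 2500 lux and 10 at 5000 lux. There glial reactivity genes (median -0.63, SD 0.94; 2 of 20 down, 4 adjusted over the list alone), interferon genes (median -0.74, SD 0.54; none of 14 past, 5 down adjusted over the list alone) and complement genes (median -0.89, SD 0.39; none of 11 past, 5 down adjusted over the list alone) lay lower in the knockout response. Their adjusted p was 7.0e-06, 7.6e-05 and 7.4e-05, and 0.38 for each with an estimated correlation. On the same contrast crystallins (median -4.16, SD 1.14, adjusted p = 0.023) were called lower, and RPE markers (median 0.64, SD 0.55, adjusted p = 0.00015), rod genes (median 0.15, SD 0.19, adjusted p = 8.2e-05) and shared photoreceptor genes (median 0.22, SD 0.44, adjusted p = 1.9e-07) higher. None of their members passed, and adjusted over the list alone 1 shared photoreceptor gene was higher; with an estimated correlation they had adjusted p = 0.78, 0.38, 0.38 and 0.29. The other 3 were microglial and chemokine genes, lower, and glycolysis, higher. None of the 10 lists was called with an estimated correlation.

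Pairs of comparisons that share arrays were checked against simulated data without any change. The genotype difference at 50 lux and the wild-type light response at 2500 lux share the 2 wild-type 50 lux arrays; 35 of the 48 probe sets higher in knockout retinas at 50 lux also rose with light in wild type, against 3.23 if independent, and 22 of 28 lower ones fell, against 1.41. Across probe sets r was 0.41, against 0.60 in the simulations, and the covariance was 0.077, against 0.033. With the knockout light response, 23 of the 48 rose further with light and 11 fell, with r at -0.18 against a simulated -0.44. Of the 19 probe sets higher in knockout retinas at 2500 lux, 10 fell in the knockout step to 5000 lux (r -0.51, against a simulated -0.45). Part of these excesses may come from the shared arrays.

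**Figure D3:**
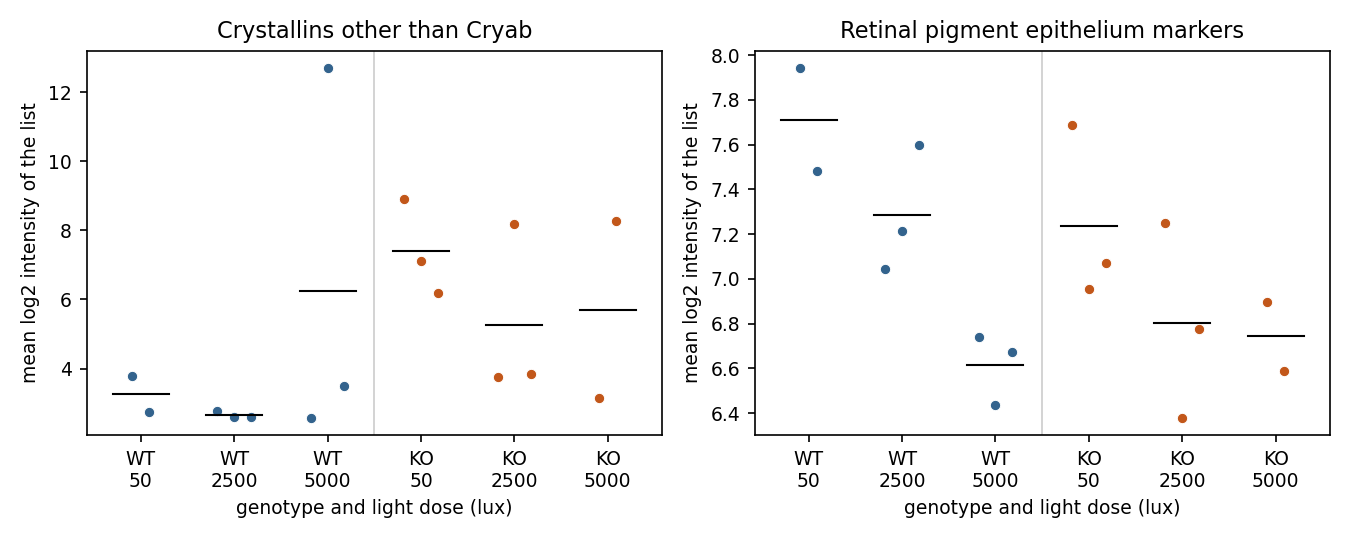
Mean log2 intensity of the crystallins other than Cryab (left) and of the RPE markers (right) on each array (points) with group means (bars), for wild-type (WT, blue) and knockout (KO, orange) retinas. The highest crystallin level, 12.7, was in wild-type 5000 lux replicate 2, and the RPE mean ran from 7.71 in wild-type retinas at 50 lux to 6.62 in wild-type retinas at 5000 lux.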

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

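Chosen only after the results were seen were the tests of RPE, lens and sex makeup and the 2 tests of the crystallins; the test of the Nxnl1 chromosome and the splits of the samples were planned.

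A light response that differed between genotypes by the interaction test singled out the following results. At 2500 lux the interaction log2 changes were -2.66 for Rnase4, -2.05 for Cebpd, -1.39 for Sox30, -3.64 for Edn2, -1.31 for Dnaaf4, -2.16 for Nudt6 and -1.82 for Zfp469. At 5000 lux they were -2.46 for Cebpd, -1.70 for Sox30, -4.01 for Edn2 and -2.59 for Nudt6. In limma 11 probe sets passed at 2500 lux and 6 at 5000 lux, and camera called 10 gene lists at 5000 lux, none of them with an estimated correlation. With 1 array left out in turn, the calls at 2500 lux of Dnaaf4, Zfp469 and Cebpd stayed past the threshold in only 3, 2 and 3 of 16 removals. Those of Edn2 and Sox30 did so in 13 and 12. At 5000 lux the call of Cebpd did so in 7 of 16.

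In knockout retinas at 50 lux 48 probe sets, with Edn2, Cebpd, Nudt6 and Sox30 among them, were higher than in wild type, by a median log2 change of 1.21 (SD 0.58). RPE carry-over as the whole cause would need more RPE signal in knockout retinas, but RPE markers tended lower there (list median log2 -0.52). With the RPE level as a covariate 110.8% of the median of the 48 was kept and all 48 still passed, which was therefore a weak test. The 28 lower probe sets were not tested this way. For DNA carried along with the targeted allele, 6.98% of the 43 other called genes lay on the chromosome of Nxnl1, against 5.59% of those tested (Fisher's exact test, one-sided, p = 0.435). This argues against such DNA as the source of most calls. The test took the whole chromosome without positions, so it cannot exclude a short stretch around Nxnl1. The called genes on the chromosome, which such DNA could still cover, were Bst2, Haus8 and Zfp469. With the crystallin level as a covariate 101.4% of the median was kept (1.23, SD 0.61), but 18 still passed at a median SE of 0.201, against 0.186 before; with the SE and degrees of freedom of before 45 passed, so the larger spread ended most of the lost calls. Carry-over of lens tissue therefore cannot be told apart from genotype for this set. All 3 knockout arrays at 50 lux had more crystallin signal than both wild-type ones. The sex covariate (100.2% kept, 1.21, SD 0.58, 26 passed at a median SE of 0.191) moved only 25 of all probe sets by over 0.1. By itself it therefore decides nothing. Y-linked minus Xist signal (log2) was -4.63, -5.02 and -5.01 on the knockout arrays at 50 lux. These values lay between those of the 2 wild-type arrays, -9.99 and -1.85. That argues against a sex difference that shifted the 48 in step with this signal. The loss of Nxnl1 stays open as an untested explanation, and the comparison rested on 2 wild-type arrays: without wild-type 50 lux replicate 2 only 9 probe sets were called in either direction.

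In knockout retinas at 2500 lux 19 probe sets, Ccl2, Aldh1a3 and Penk among them, were higher than in wild type, by a median log2 change of 1.86 (SD 0.57). The sex covariate, with 99.84% of the median kept and 12 passed, moved only 25 of all probe sets by over 0.1 here. Y-linked minus Xist signal was 5.29, -9.73 and -9.74 on the knockout arrays and -9.83, -2.12 and -5.28 on the wild-type ones. The knockout arrays did not all lie to 1 side, but with so wide a spread sex makeup stays open. With the RPE covariate 100.8% was kept (1.87, SD 0.59) and 3 passed, and with the crystallin covariate 100.5% was kept (1.87, SD 0.59) and 9 passed; the median SE was 0.250 before and 0.294 and 0.274 after, and with the SE and degrees of freedom of before all 19 passed in each, so the larger spread ended the calls. Both kinds of carry-over cannot be told apart from genotype here, because too few calls outlasted the added uncertainty. Of the 10 splits of the 6 arrays the real one gave 22 calls and the highest other 1, and 10 splits are too few for a share under 0.05 (1 gave as many as the real one, itself).

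Crystallins other than Cryab differed between arrays, from a mean log2 level of 2.57 to 12.7. In knockout retinas at 50 lux they lay at 6.17 to 8.91, above every wild-type array but the highest. Against a level set by the Nxnl1 genotype alone, 2 of the 8 knockout arrays lay within the range of the 7 wild-type arrays other than the highest (2.57 to 3.78), and the highest array of all was wild type, at 5000 lux. Lens tissue of the makeup of that array may be the source in the knockout arrays at 50 lux, but the excess of gamma over beta crystallins relative to it averaged -0.91 there (replicates -1.40 and -1.03 from 3 gamma crystallins each, and -0.29 from 1), which does not decide. The lens fibre markers Mip, Lim2 and Bfsp1 reached 8.23, 7.87 and 8.62 in wild-type 5000 lux replicate 2, and in the knockout arrays at 50 lux at most 2.27, 2.46 and 3.93; Grifin was at 7.88 in the former and at 4.43, 2.23 and 2.77 in knockout 50 lux replicates 1, 2 and 3. In knockout 50 lux replicates 1, 2 and 3 the beta crystallins were at -3.45, -5.41 and -5.62 (log2) relative to the highest array. The gamma crystallins were at -4.85, -6.44 and -5.91. A like fall would bring the lens fibre markers near the lowest value, so their low level cannot decide. Whether the crystallin signal in the knockout arrays at 50 lux came from lens tissue or from retinal cells stays open.

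For the knockout light response at 2500 lux, 1 of 10 splits of the 6 arrays, the real one with 4501 calls, gave as many, and the highest other gave 0; for the wild-type step from 2500 to 5000 lux the real split gave 0 calls, all 10 splits gave as many, and the highest other gave 8. In both, 10 splits are too few for a share under 0.05. For the genotype difference averaged over doses 7 of 100 splits that exchanged genotypes within doses gave as many as the real 4 calls, so chance cannot be excluded for that count. These splits took no account of the replicate numbers; with the numbers as a block the real count was 7. One of them gave 283 calls, many times the real count, which points to a structure of the samples; what it is was not tested.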

How the results depend on the processing

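Chosen only after the data were seen were the crystallin covariate, the RPE covariate and the removal of 2 arrays in doubt; the other alternatives were planned. With the same probe sets, no named gene past the threshold and no called gene list reversed its direction in any alternative run. Other probe sets had the opposite sign in 11 pairs, 6 of them for Cp and the others for Sod2, Bhlhe41, Arntl, Srxn1 and Lrrfip1. Of the results for named genes 4808 kept their side of the threshold and 721 became weaker, and for called gene lists 1216 kept it and 86 became weaker. Counts that moved by over 1.5 times follow, and the cause was not tested unless stated. With only the arrays of the compared groups in the fit, which leaves fewer arrays to estimate the spread, the count was 1275 for wild-type light at 2500 lux, 182 for knockout light at 5000 lux, 0 for the knockout dose step, 1, 4 and 0 for genotype at 50, 2500 and 5000 lux, and 6 and 1 for the interactions at 2500 and 5000 lux. With no filter, which adds dim probe sets, it was 1526 for knockout light at 5000 lux, 141 and 3 for genotype at 50 and 5000 lux, 37 for genotype over the doses, and 47 and 39 for the interactions. With a filter at log2 6 it was 10 for the knockout dose step and 5 for genotype at 2500 lux. Array weights gave 5512 for wild-type light at 5000 lux, 6791 and 730 for knockout light at 2500 and 5000 lux, 1 for the knockout dose step, 248 and 39 for genotype at 50 and 2500 lux, and 22 for the interaction at 2500 lux. The replicate block gave 4613 for knockout light at 5000 lux, 7 for genotype over the doses and 27 for the interaction at 2500 lux. The sex covariate gave 37 for genotype at 50 lux, 2 over the doses and 5 for the interaction at 2500 lux. The RPE covariate gave 1336 for knockout light at 5000 lux, 535, 4 and 9 for genotype at 50 lux, at 2500 lux and over the doses, and 20 for the interaction at 5000 lux. The crystallin covariate gave 32 for the knockout dose step, 34 and 12 for genotype at 50 and 2500 lux, and 5 for the interaction at 2500 lux. Without the 2 arrays in doubt it was 1351 for knockout light at 5000 lux, 32 for the knockout dose step, and 21 and 4 for genotype at 50 and 2500 lux. With log2 of the value plus 16 it was 2 for genotype over the doses and 4 for the interaction at 2500 lux, and with an intensity trend 7 for the latter.

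Where both counts were at least 10, the share of calls that were rises moved by over 10 points as follows. For knockout light at 5000 lux it went from 48.5% to 90.7% with only the arrays of the compared groups, to 65.2% with array weights and to 62.2% with the RPE covariate, and for wild-type light at 5000 lux from 56.9% to 70.5% with the RPE covariate. For the knockout dose step it went from 5.56% to 29.2% with no filter, to 16.7% with an intensity trend, and to 15.6% with the crystallin covariate and without the 2 arrays in doubt. For genotype at 50 lux it went from 63.2% to 33.3% with no filter and to 76.2% without the 2 arrays in doubt, for genotype at 2500 lux from 86.4% to 75.0% with the sex covariate, and for the interaction at 2500 lux from 27.3% to 78.7% with no filter. With single arrays left out it went, for wild-type light, from 57.1% to 69.7% at 2500 lux and from 56.9% to 72.2% at 5000 lux without wild-type 50 lux replicate 1, and for knockout light at 5000 lux from 48.5% to 66.6% without knockout 5000 lux replicate 2. For the knockout dose step it went from 5.56% to 45.6% without knockout 5000 lux replicate 1 and to 17.2% without wild-type 2500 lux replicate 3. For genotype at 50 lux it went from 63.2% to 36.9% without knockout 50 lux replicate 2 and to 79.2% without replicate 1, and for genotype at 2500 lux from 86.4% to 71.4% without knockout 2500 lux replicate 1. For the interaction at 2500 lux it went from 27.3% to 53.3% without wild-type 2500 lux replicate 3, to 46.2% without knockout 50 lux replicate 2 and to 40.0% without wild-type 5000 lux replicate 2. Smaller counts moved as well: the interaction at 5000 lux went from 0% of 6 calls to 79.5% of 39 with no filter. Quantile normalization applied again moved no count by over 1.5 times.

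Leaving out each array in turn, a group left with 1 array was assumed to vary like the others. Wild-type light gave 1127 (without wild-type 50 lux replicate 1) to 3001 at 2500 lux and 1025 (without the same array) to 2679 at 5000 lux, both highest without knockout 50 lux replicate 1. Knockout light gave 2918 (without knockout 2500 lux replicate 3) to 4751 at 2500 lux, and 575 (without knockout 5000 lux replicate 2) to 4411 (without replicate 1) at 5000 lux. The wild-type dose step gave 0 to 30 (without wild-type 5000 lux replicate 1), and the knockout step 0 (without knockout 5000 lux replicate 2) to 103 (without replicate 1). Genotype gave 9 (without wild-type 50 lux replicate 2) to 363 (without knockout 50 lux replicate 2) at 50 lux, 2 to 86 (without wild-type 2500 lux replicates 1 and 3 in turn) at 2500 lux, 1 to 9 (without knockout 5000 lux replicate 1) at 5000 lux, and 2 to 10 (without wild-type 2500 lux replicates 2 and 3 in turn) over the doses. The interactions gave 3 to 15 at 2500 lux (without wild-type 50 lux replicate 1 and wild-type 2500 lux replicate 3 in turn) and 4 to 14 at 5000 lux (without wild-type 50 lux replicate 2 and knockout 5000 lux replicate 1 in turn), and gene list calls over all comparisons 97 to 112, against 101 with all arrays. Arrays of different groups were also correlated after the group means were removed. As a hint that the replicate numbers carry some structure, 13 of 16 arrays correlated best with an array of their own number. Of 36 pairs with the same number 21 had r over 0.1 (from -0.24 to 0.69). These pairs are not independent, since what is left within a group sums to 0, and the arrays of a 2-array group mirror each other. Dim probe sets limit the signal over background, since about 31% of the values of each array lay at the lowest value.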

Other observations

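Knockout retinas at 2500 lux (n = 3 against 3) held further large rises. The interferon-induced GTPase gene Irgm1 rose at least 13.6-fold (adjusted p = 6.6e-07) and the peptide transporter Tap1 at least 8.95-fold. Timp1, an inhibitor of matrix proteases, rose at least 7.01-fold, and Steap4, a metalloreductase, at least 10.2-fold. In wild-type retinas the troponin gene Tnnt2 rose at least 7.99-fold at 2500 lux and at least 10.9-fold at 5000 lux, and in knockout retinas at least 8.41-fold at 5000 lux.

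The bipolar cell transcription factor Vsx1 fell in wild-type retinas at 5000 lux (log2 -0.93, SE 0.27, adjusted p = 0.040) and in knockout retinas at 2500 lux (log2 -1.26, SE 0.24, adjusted p = 0.0023) and 5000 lux (log2 -1.03, SE 0.27, adjusted p = 0.026). The bipolar channel gene Trpm1 rose at least 5.18-fold in knockout retinas at 2500 lux (adjusted p = 0.00050). Bhlhe40, a repressor of the clock, rose in wild-type retinas at both doses (log2 0.90, SE 0.20, adjusted p = 0.011, and log2 0.70, SE 0.20, adjusted p = 0.044) and in knockout retinas at 2500 lux (log2 0.81, SE 0.18, adjusted p = 0.0070). Kdr, a receptor for vascular growth factor, rose in all 4 light comparisons, by 0.63 to 1.21 on the log2 scale. With single arrays left out, the Vsx1 calls in wild-type retinas at 5000 lux (without wild-type 50 lux replicate 2, adjusted p = 0.24) and in knockout retinas at 5000 lux (without knockout 5000 lux replicate 2, adjusted p = 0.32) ended, and so did the Bhlhe40 calls in wild-type retinas at 2500 and 5000 lux (without wild-type 50 lux replicate 1, adjusted p = 0.083 and 0.21), and the Kdr call in knockout retinas at 5000 lux (without knockout 5000 lux replicate 2, adjusted p = 0.16).

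By Y-linked and Xist signal, 10 arrays held both, 5 lacked the Y-linked signal and 1 lacked Xist, while the labels give both sexes in equal number; wild-type and knockout groups both had arrays of more than 1 kind. Other probe sets of the named genes were compared, comparison by comparison: 119 gave the same call, 58 had the same sign without passing, 11 had the opposite sign, and in 745 the named probe set itself had not passed. List median, mean and camera direction differed in sign in 52 lists over all 12 comparisons; none of these was called, and the smallest adjusted p among them was 0.062.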
